A study of Mus musculus with 39 samples.

How the data were processed

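Total RNA of mouse liver was sequenced in 36 libraries, 3 in each of 12 groups given by genotype, time and oxygen. The series lists 39 samples, and the 3 double-knockout samples, which have no columns in the table, are not analysed here. Per the labels, the authors' deposited raw columns hold the read count of each gene in each library, and no step was applied to these counts after counting. The deposited normalized columns hold a signal that the authors made by dividing the raw counts by a size factor, and each such column was found to be its raw column times a constant (largest relative range within a library 9.7e-15). Only the raw counts were used for tests. The submitters' processing notes name cutadapt, STAR 2.4.2a, HTSeq, DESeq2 and the mm10 genome. They do not state the strand, the library type, the use of molecular identifiers, or the filter that left the genes of the table. Gene positions came from the GRCm38 annotation (GENCODE M21), matched by symbol for 98.5% of tested genes.

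The floor used for a group at 0, 3 counts over the 3 libraries of HLKO CT4 21%, corresponds to 0.362 CPM. Replicates differed by more than counting error in every pair (chi-square per degree of freedom 3.533 to 28.08). In the control groups Alb CT4 21% A stood apart (21.46 and 19.73 against B and C, 5.326 between B and C), as did Alb CT16 6% A (28.08 and 21.39, against 3.92). The replicate letters were checked for pairing between groups and showed none: 0 of 13 comparisons had all 3 same-letter correlations over 0.1, and the letters were therefore not used as pairs.

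Genes were kept by filterByExpr with a count minimum of 10, which left 9483. Counts were scaled by TMM and fitted over all 36 libraries with quasi-likelihood models in edgeR 4.0.16 (R 4.3.3). The 22 comparisons were hypoxia in each genotype and time, their differences between times and genotypes, genotype at 21% oxygen, and time at 21% oxygen. The p-values of each comparison were adjusted by Benjamini and Hochberg, and a gene is called at an adjusted p under 0.05. The 34 gene lists, written before the values were seen, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, and 30 had at least 3 tested members. Those for lymphocytes, neutrophils, pancreas and mitochondrially encoded genes had 2, 1, 2 and 0 tested members and could not be tested. DESeq2 1.42.0 served as the alternative test, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

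The fit was tested on simulated data that had the depth and dispersion of these libraries and the same mean level in every group apart from the changes put in. It recovered 67% of genes changed 2-fold and 93% of genes changed 4-fold for hypoxia in Alb at CT4, with 8 false calls among 176. For the time dependence of hypoxia in Alb it recovered 41% and 77%, and for the 3-way difference of HLKO 15% and 49%. A comparison simulated without change gave 0 calls.

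The genes named in the report came from a rule. It gave 8 genes fixed in advance, up to 6 called genes with the highest and 6 with the lowest fold change in each comparison, with a mean of at least 5 CPM in a group and no overlap between replicates, and the 2 to 4 largest called members of each list. Among the genes the rule gave, the text names mainly those that kept their call when each library was left out, a choice made after the values were seen. Some genes the rule gave are not reported here. Alternatives fixed in advance were DESeq2, RLE normalization, no low-count filter, a fit on the compared groups only, a replicate block, leaving out each library, an estimated correlation for lists, and a threshold of 0.01 for overlaps. The closing section gives their effect.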

Results

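The series holds RNA sequencing of livers from C57BL/6 mice aged 3 to 5 months. The mice were Alb-Cre controls (Alb), mice lacking Hif1a in hepatocytes (HLKO) or mice lacking Bmal1, whose gene symbol is Arntl, in hepatocytes (BLKO). They breathed 21% or 6% oxygen for 4 h on a day without lights after 2 weeks in 12 h of light per day. Exposure started at circadian time 4 (CT4) or 16 (CT16) and ended at CT8 or CT20. Genotype, time and oxygen gave 12 groups of 3 libraries, 36 in all, each named here by its group and its replicate letter, as in Alb CT4 21% A. The table lists raw counts per gene symbol, and library totals ran from 1717589 counts in HLKO CT16 6% A to 5196957 counts in BLKO CT16 21% A. Between 10813 and 11693 genes had at least 1 count in a library, and the 10 most abundant genes took 15.35% to 20.83% of the counts. Of the symbols, 11664 (98.2%) matched the mouse annotation, from which positions are given. Levels below are mean CPM (counts scaled to a common library size) ± SD and changes are log2 fold changes ± SE, with n = 3 libraries per group throughout. The adjusted p-values of genes come from edgeR over 9483 tested genes, are two-sided, and are adjusted within each comparison. For every called gene named in a comparison of 2 groups, all 3 libraries of one group lay above all 3 of the other, which chance gives in 10% of genes. No label tells whether molecular identifiers were used, so floors cover counting error only.

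Hif1a (chromosome 12, 73901375 to 73947530), the oxygen-regulated transcription factor deleted in HLKO, was low in all groups. Group means ran from 2.29 ± 2.39 CPM in HLKO CT16 6% to 8.87 ± 5.39 CPM in Alb CT16 6%, and single libraries held 0 to 74 counts. At 21% oxygen Hif1a was at 5.24 ± 2.38 CPM in HLKO and 8.27 ± 2.42 CPM in Alb at CT4 (-0.61 ± 0.45, adjusted p = 0.409), and at 5.50 ± 2.5 and 5.65 ± 1.39 CPM at CT16 (-0.03 ± 0.46, adjusted p = 0.985). Hif1a was called in 0 of 22 comparisons by edgeR and in 0 by DESeq2, with 8 at an unadjusted p under 0.05. Arntl (chromosome 7, 113207465 to 113314126), the clock transcription factor deleted in BLKO, was at 6.43 ± 0.46 CPM in BLKO and 4.49 ± 1.87 CPM in Alb at CT4 21% (0.52 ± 0.36, adjusted p = 0.487). At CT16 21% it was at 11.9 ± 1.76 CPM in BLKO and 19.7 ± 2.3 CPM in Alb (-0.75 ± 0.25, adjusted p = 0.0818, and 0.0409 in a fit on the compared groups only). Counts were deposited per gene, and reads outside the deleted part are counted with the rest, so these levels check neither knockout label. The targets of Arntl separated the BLKO label. At CT4 21% Dbp (chromosome 7, 45705088 to 45710203), a clock-driven transcription factor, stood at 11.1 ± 1.56 CPM in BLKO and 179 ± 24.3 CPM in Alb (fell by 3.99 ± 0.43, adjusted p = 7.85e-08), and Nr1d1, the clock repressor REV-ERB alpha, at 13.1 ± 8.94 against 107 ± 33.0 CPM (fell by 3.03 ± 0.32, adjusted p = 6.97e-08). Among the other genes fixed in advance, edgeR called Per1 in 7 of 22 comparisons, Dbp in 6, Arntl in 5, Nr1d1 in 4 and Epas1, the second oxygen-regulated factor of liver, in 2. The growth factor Vegfa was called in 0 (lowest adjusted p = 0.0535, 6 at an unadjusted p under 0.05, 1 called by DESeq2), as was Per2 (lowest adjusted p = 0.132, 2 at an unadjusted p under 0.05, 0 called by DESeq2).

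**Figure D1:**
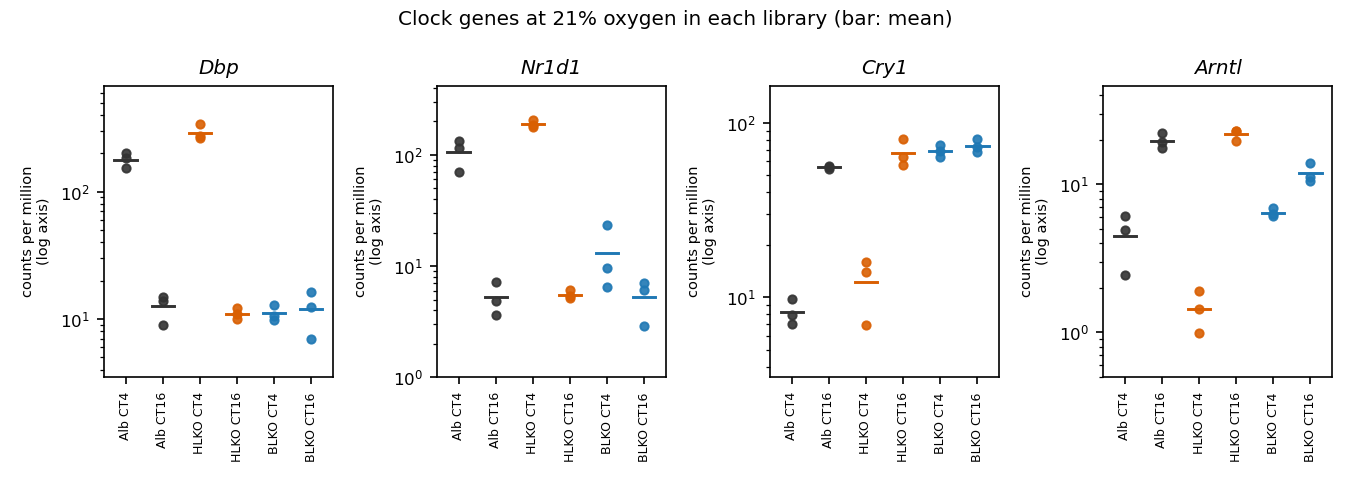
CPM on a log axis for 4 clock genes in each library at 21% oxygen, with a bar at each group mean. Dbp falls between CT4 and CT16 from 179 to 12.6 CPM in Alb and from 291 to 11.0 CPM in HLKO, and stands at 11.1 and 11.9 CPM in BLKO.

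Time of day at 21% oxygen was compared within each genotype, which also checks the time labels. In Alb livers the clock genes took opposite phases. From CT4 to CT16 Nr1d1 fell by 4.38 ± 0.36 (107 ± 33.0 to 5.24 ± 1.81 CPM, adjusted p = 3.35e-10) and Dbp fell by 3.82 ± 0.41 (adjusted p = 2.5e-07). Arntl rose by 2.14 ± 0.30 (4.49 ± 1.87 to 19.7 ± 2.3 CPM, adjusted p = 5.49e-05), as did Cry1, a clock repressor, by 2.74 ± 0.22 (adjusted p = 2.26e-10). Cdkn1a, the cell cycle inhibitor p21, rose by 2.05 ± 0.20, while Sort1, a sorting receptor, fell by 1.63 ± 0.26. Of 5 tested clock genes repressed by REV-ERB, 4 rose, also when adjusted over the list alone (median 1.91, adjusted p = 2.69e-37). Of 12 clock genes driven by BMAL1, 4 fell, or 5 adjusted over the list alone (median -0.11, adjusted p = 1.79e-08). In all 120 genes differed, 67 higher and 53 lower at CT16. The count was 68 without Alb CT4 21% A, 45 without C, 56 without Alb CT16 21% A, 70 without B and 39 without C, and it was 69 in a fit on the compared groups only.

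HLKO livers showed a broader difference between the times at 21% oxygen, with 1125 genes called, 623 higher and 502 lower at CT16. No label gives the feeding state of the mice or the day of collection. Clock genes were among them: Nr1d1 fell by 5.08 ± 0.36 (adjusted p = 1.01e-11), Dbp fell by 4.72 ± 0.43 (adjusted p = 2.72e-09), and Arntl rose by 3.88 ± 0.38 (adjusted p = 1.34e-08). Among fat-burning genes, Cyp4a14 and Cyp4a10, fatty acid hydroxylases whose reads may be shared between paralogs, rose by 7.78 ± 1.43 and 5.74 ± 0.95, and Pdk4, which restrains glucose oxidation, rose by 4.38 ± 0.64 (2.69 ± 0.87 to 58.0 ± 31.0 CPM). Of 28 genes of fatty acid oxidation and PPARA targets 19 rose, with 21 higher and 1 lower adjusted over the list alone (median 0.69, adjusted p = 2.35e-18). Of 13 glucocorticoid targets 10 rose, or 11 adjusted over the list alone (median 1.31, adjusted p = 1.94e-26). Among them were Cdkn1a (4.18 ± 0.20, 10.4 ± 1.85 to 187 ± 16.5 CPM), Tat, which breaks down tyrosine (2.45 ± 0.19), and Per1, a clock repressor (1.11 ± 0.24, adjusted p = 0.00212). Of 21 genes of gluconeogenesis and amino acid breakdown 12 rose and 1 fell, with 14 and 1 adjusted over the list alone (median 0.49, adjusted p = 3.19e-13). They included G6pc, which releases free glucose (1.89 ± 0.30), and Irs2, an insulin signalling adaptor (2.07 ± 0.41). Among 5 tested clock genes repressed by REV-ERB 4 rose, and 5 did so adjusted over the list alone (adjusted p = 8.25e-21). Of 12 clock genes driven by BMAL1, 3 rose and 3 fell, with 3 and 4 adjusted over the list alone (median -0.22, adjusted p = 0.00581, and adjusted p = 0.129 with an estimated correlation). Markers of other cells were also higher at CT16: 2 of 4 red cell markers, also adjusted over the list alone (median 1.64, adjusted p = 0.00228, and adjusted p = 0.129 with an estimated correlation), and 1 of 16 liver endothelial markers, or 0 adjusted over the list alone (median 0.33, adjusted p = 0.0213, and adjusted p = 0.424 with an estimated correlation). Acot1, a thioesterase with close paralogs, rose by 3.67 ± 0.45, and Camk2b, a calcium-dependent kinase, fell by 4.23 ± 0.84. The count was 737 without HLKO CT4 21% C and 677 without HLKO CT16 21% B. Whether the time effect at 21% oxygen differed between HLKO and Alb was not tested directly.

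In BLKO livers Dbp, Nr1d1 and Arntl did not pass the test between the times. Dbp was at 11.1 ± 1.56 CPM at CT4 and 11.9 ± 4.75 CPM at CT16 (0.12 ± 0.48, adjusted p = 0.938). Nr1d1 was at 13.1 ± 8.94 and 5.32 ± 2.16 CPM (-1.25 ± 0.40, adjusted p = 0.0963, and 0.035 by DESeq2), and Arntl at 6.43 ± 0.46 and 11.9 ± 1.76 CPM (0.87 ± 0.30, adjusted p = 0.13). The metal-binding metallothioneins Mt1 and Mt2 were lower at CT16, where Mt1 fell by 5.17 ± 0.65 (2523 ± 1320 to 70.1 ± 15 CPM) and Mt2 fell by 5.85 ± 0.77 (3205 ± 2070 to 55.7 ± 20.9 CPM). Egr1, an immediate early transcription factor, fell by 3.36 ± 0.44 and Tacc2, a centrosomal protein, by 2.49 ± 0.36, whereas Sgk1, a stress-responsive kinase, rose by 1.62 ± 0.26 (adjusted p = 0.000411). Of 25 acute phase proteins 7 fell, or 8 adjusted over the list alone (median -0.80, adjusted p = 4.28e-12, and adjusted p = 0.587 with an estimated correlation). In all 208 genes differed, 81 higher and 127 lower at CT16. The count was 73 without BLKO CT4 21% A, 106 without B and 127 without C, and 116 and 106 without BLKO CT16 21% B and C. The time effect at 21% oxygen was not tested for a difference between BLKO and Alb.

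The effect of Hif1a loss at 21% oxygen was taken from HLKO against Alb. Several of the most changed genes were shared by the times. Serpina3c (chromosome 12, 104146382 to 104153870), a liver protease inhibitor with close paralogs, was at 566 ± 104 CPM in HLKO and 6.87 ± 3.14 CPM in Alb at CT4 (6.35 ± 0.39, adjusted p = 2.95e-13) and at 439 ± 162 against 7.46 ± 1.72 CPM at CT16 (5.85 ± 0.38, adjusted p = 8.15e-13). Gdpd3, a lysophospholipase, rose by 4.35 ± 0.58 at CT4 and 6.41 ± 0.67 at CT16. Trim12a (chromosome 7, 104299894 to 104315466), a tripartite motif gene, had 0 counts in HLKO CT4 21% and 89 counts over the Alb CT4 21% libraries (9.52 ± 1.65 CPM), at least 26.3-fold lower against a floor of 3 counts over the group. At CT16 21% Trim12a was at 0.26 ± 0.23 CPM in HLKO and 7.34 ± 1.90 CPM in Alb. DESeq2 gave Trim12a no adjusted p in either comparison of HLKO with Alb. At CT4, Serpina3h rose by 4.95 ± 0.51 and Abhd1, a hydrolase, by 4.61 ± 0.52, and Mug2, a protease inhibitor with paralogs, fell by 4.13 ± 0.54 (17.3 ± 4.44 against 299 ± 37.8 CPM). At CT16, Rad51b (chromosome 12, 79297282 to 79814690), a DNA repair gene, rose by 4.87 ± 0.27 (124 ± 13.0 against 4.49 ± 2.94 CPM), and Serpina1e (chromosome 12, 103946931 to 103958975) fell by 3.95 ± 0.42 (852 ± 233 against 13140 ± 2290 CPM). Pttg1, a regulator of chromosome separation, fell by 3.02 ± 0.39 at CT16. Genes called in the same direction at both times numbered 95, of which 93 had a position. Of these 16 (17.2%) lay on chromosome 12, which carries 3.54% of tested genes.

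**Figure D2:**
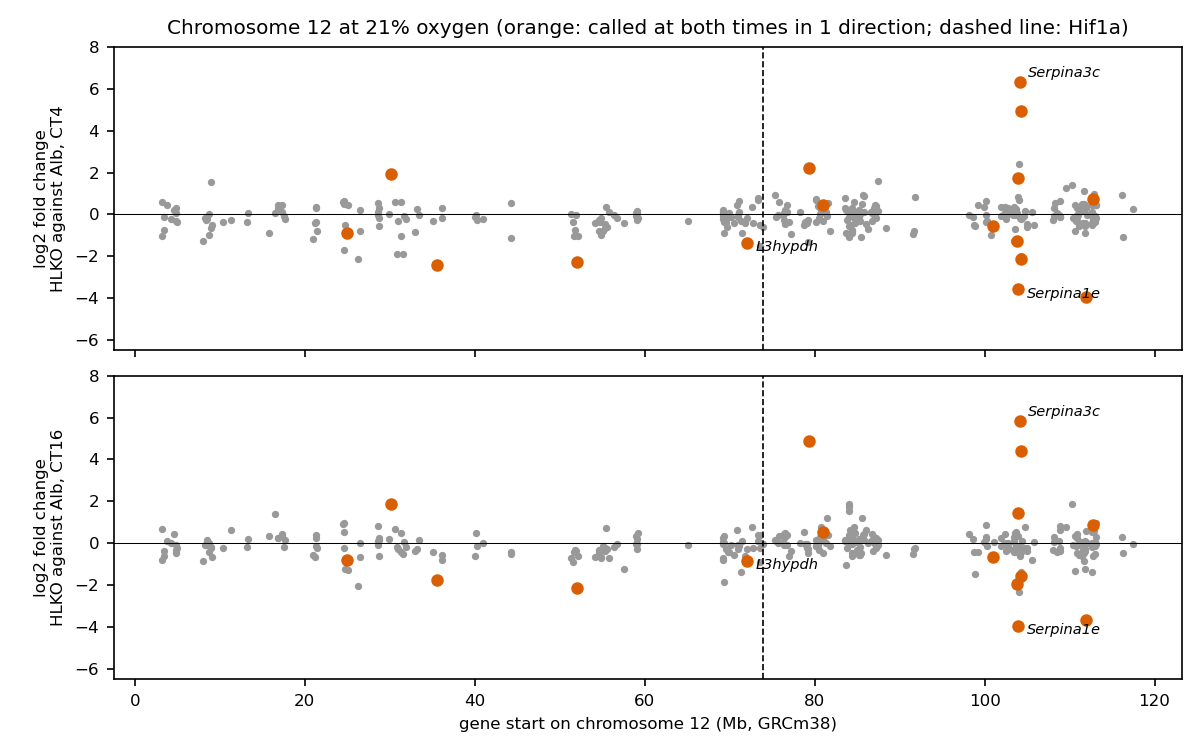
Log2 fold change of HLKO against Alb at 21% oxygen for each tested gene along chromosome 12 (position in Mb, GRCm38) at CT4 and CT16, with called genes marked and the position of Hif1a drawn as a line. Serpina3c stands at 6.35 and 5.85 near 104 Mb.

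Beyond these genes, HLKO livers at CT16 21% had higher glucocorticoid targets: 6 of 13 rose, or 10 adjusted over the list alone (median 1.09, adjusted p = 3.72e-17). They included Cdkn1a (1.99 ± 0.17, 187 ± 16.5 against 46.9 ± 10.7 CPM), Tat (1.52 ± 0.19), Per1 (1.36 ± 0.24) and Fkbp5, a co-chaperone of the glucocorticoid receptor (1.19 ± 0.22, adjusted p = 0.000848). Pdk4 rose by 2.20 ± 0.49 (adjusted p = 0.00712), a call lost without Alb CT16 21% A (adjusted p = 0.0606) or HLKO CT16 21% B (adjusted p = 0.0892). Epas1 rose by 0.61 ± 0.13 (163 ± 25.1 against 107.5 ± 9.64 CPM, adjusted p = 0.00417), also lost without HLKO CT16 21% B (adjusted p = 0.055). Genes of gluconeogenesis and amino acid breakdown rose in 4 of 21 cases, with 6 higher and 1 lower adjusted over the list alone (median 0.30, adjusted p = 0.000283, and adjusted p = 0.0758 with an estimated correlation). At CT4 21%, 8 of 28 genes of fatty acid oxidation and PPARA targets fell and 1 rose in HLKO, with 13 lower and 2 higher adjusted over the list alone (median -0.40, adjusted p = 0.00104, and adjusted p = 0.71 with an estimated correlation). In the same comparison 2 of 4 red cell markers were lower, or 3 adjusted over the list alone (median -1.64, adjusted p = 0.00104, and adjusted p = 0.485 with an estimated correlation). At CT16 21% 1 of 11 stellate cell and fibroblast markers was higher in HLKO, also adjusted over the list alone (median 0.61, adjusted p = 0.0117, and adjusted p = 0.586 with an estimated correlation). Arntl fell by 1.60 ± 0.48 at CT4 21% (1.44 ± 0.46 against 4.49 ± 1.87 CPM, adjusted p = 0.0321) and was at 21.9 ± 1.84 against 19.7 ± 2.3 CPM at CT16 (0.14 ± 0.25, adjusted p = 0.816). The CT4 call of Arntl ended without Alb CT4 21% A (adjusted p = 0.0682) or B (0.184), or without HLKO CT4 21% A (0.0769), B (0.0577) or C (0.127). Nr1d1 at CT4 rose by 0.83 ± 0.26 (189 ± 16.2 against 107 ± 33.0 CPM, adjusted p = 0.0426). That call of Nr1d1 was lost with DESeq2 (adjusted p = 0.0519), with a replicate block (0.0532), without Alb CT4 21% A (0.0643) or B (0.242), and without HLKO CT4 21% A (0.081), B (0.123) or C (0.0739). In all 921 genes differed at CT4 (389 higher, 532 lower in HLKO) and 338 at CT16 (195 higher, 143 lower). The CT4 count was 277 without Alb CT4 21% B and 444, 453 and 445 without HLKO CT4 21% A, B and C. The CT16 count was 126 and 163 without Alb CT16 21% A and C, and 169 and 147 without HLKO CT16 21% B and C. Whether the difference between HLKO and Alb at 21% oxygen depends on the time was not tested.

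The effect of Bmal1 loss at 21% oxygen was taken from BLKO against Alb. At CT4 several clock output genes were lower and several genes that REV-ERB represses were higher. Besides Dbp and Nr1d1, Nr1d2, the second REV-ERB, fell by 3.83 ± 0.60 and Ciart, a clock repressor, by 2.95 ± 0.61 (adjusted p = 0.00152). Of 12 clock genes driven by BMAL1, 6 fell and 1 rose, with 8 lower and 1 higher adjusted over the list alone (median -1.17, adjusted p = 5.57e-11). Of 5 clock genes repressed by REV-ERB, 4 rose, also adjusted over the list alone (median 1.92, adjusted p = 1.26e-23), among them Npas2, a partner of BMAL1 in the clock (4.31 ± 0.46, 22.1 ± 7.60 against 1.10 ± 0.60 CPM), and Cry1 (3.05 ± 0.22). Among 13 glucocorticoid targets 5 rose, or 6 adjusted over the list alone (median 0.36, adjusted p = 8.7e-09), with Cdkn1a at 206 ± 11.0 against 11.4 ± 1.07 CPM (4.17 ± 0.20, adjusted p = 2.16e-16) and Mt2 at 3205 ± 2070 against 192 ± 188 CPM (4.06 ± 0.70, adjusted p = 0.00018). Of 16 genes of fatty acid synthesis 8 fell, also adjusted over the list alone (median -0.58, adjusted p = 3.25e-07, and adjusted p = 0.187 with an estimated correlation), such as Me1, which makes NADPH (-1.58 ± 0.36), and Thrsp, a lipogenic regulator (-1.32 ± 0.23). Slc34a2, a phosphate transporter (4.89 ± 0.63), and Loxl4, a lysyl oxidase (4.54 ± 0.39), rose, and Cyp17a1, a steroid hydroxylase, fell by 3.97 ± 0.70 (adjusted p = 0.000255). Trim12a was at 0.16 ± 0.27 against 9.52 ± 1.65 CPM. At CT4, 706 genes differed, 358 higher and 348 lower in BLKO. The count was 439 and 469 without Alb CT4 21% B and C, and 423 without BLKO CT4 21% A.

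At CT16 21% Dbp (11.9 ± 4.75 against 12.6 ± 3.22 CPM, adjusted p = 0.984) and Nr1d1 (5.32 ± 2.16 against 5.24 ± 1.81 CPM, adjusted p = 0.952) did not pass the test between BLKO and Alb. Some genes of fat metabolism did. Of 28 genes of fatty acid oxidation and PPARA targets 10 fell in BLKO, or 15 adjusted over the list alone (median -0.45, adjusted p = 7e-12, and adjusted p = 0.172 with an estimated correlation). Of 16 genes of fatty acid synthesis 7 fell and 1 rose, with 9 and 1 adjusted over the list alone (median -0.47, adjusted p = 1.68e-08, and adjusted p = 0.172 with an estimated correlation), such as Thrsp (-1.76 ± 0.23) and Pklr, the liver pyruvate kinase (-1.56 ± 0.25). Of 24 cholesterol synthesis genes 5 rose, or 10 adjusted over the list alone (median 0.39, adjusted p = 5.45e-06, and adjusted p = 0.319 with an estimated correlation). The largest falls included Acot3, an acyl-CoA thioesterase (-4.21 ± 0.77), Cyp46a1, a cholesterol hydroxylase (-3.31 ± 0.60), and Cyp2a5, a xenobiotic oxidase (-2.86 ± 0.36). Slc34a2 (4.14 ± 0.71), the neurotrophin receptor Ntrk2 (4.04 ± 0.79), Cyp2c55 (3.70 ± 0.45) and Lpl, lipoprotein lipase (3.66 ± 0.55), rose. Trim12a was at 0.25 ± 0.30 against 7.34 ± 1.90 CPM. In all 510 genes differed at CT16, 203 higher and 307 lower in BLKO. The count was 328 and 321 without Alb CT16 21% B and C, and 270 without BLKO CT16 21% B. No test compared the BLKO differences of CT4 with those of CT16.

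The liver response to 6% oxygen in control mice was measured first at CT4. Some hypoxia-inducible genes rose in Alb livers: Ddit4, an inhibitor of mTOR signalling, rose by 4.46 ± 0.47, Igfbp1 (chromosome 11, 7197782 to 7202546), which binds insulin-like growth factors, by 4.38 ± 0.38 (94.2 ± 48.8 to 1959 ± 313 CPM, adjusted p = 9.66e-10), and Hilpda, a lipid droplet protein, by 3.54 ± 0.63. Of 29 HIF targets outside glycolysis 11 rose, or 12 adjusted over the list alone (median 0.41, adjusted p = 9.23e-08), among them Ankrd37 (2.33 ± 0.41), while Vegfa was at 157 ± 19.8 against 122 ± 11.7 CPM (0.37 ± 0.21, adjusted p = 0.3). Of 18 genes of glycolysis and glucose uptake 4 rose and 1 fell, also adjusted over the list alone (median 0.24, adjusted p = 0.0356, and adjusted p = 0.1 with an estimated correlation), with the glucose transporter Slc2a1 at 1.38 ± 0.23 and the pyruvate kinase Pkm at 1.30 ± 0.23. Of 18 immediate early genes 10 rose, with 11 higher and 1 lower adjusted over the list alone (median 1.27, adjusted p = 2.46e-11), such as Nr4a1 (3.70 ± 0.40), Atf3 (3.25 ± 0.71) and Btg2 (2.94 ± 0.44). Among 13 Kupffer cell and macrophage markers 9 were higher at 6% oxygen, or 11 adjusted over the list alone (median 1.13, adjusted p = 2.2e-07, and adjusted p = 0.124 with an estimated correlation), for example C1qc at 80.2 ± 27.3 against 34.0 ± 12.5 CPM. Among 16 liver endothelial markers 6 were higher, or 7 adjusted over the list alone (median 0.55, adjusted p = 1.6e-05, and adjusted p = 0.117 with an estimated correlation), for example Kdr at 30.5 ± 7.78 against 12.5 ± 1.73 CPM.

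Glucocorticoid targets rose in the same Alb CT4 comparison in 5 of 13 cases, also adjusted over the list alone (median 0.15, adjusted p = 1.37e-08). Cdkn1a (chromosome 17, 29090976 to 29100727) rose by 3.88 ± 0.20 (11.4 ± 1.07 to 168 ± 17.0 CPM, adjusted p = 1.67e-15), Mt2 (chromosome 8, 94172664 to 94173568) by 4.38 ± 0.71 (192 ± 188 to 3999 ± 1040 CPM), Sgk1 by 2.52 ± 0.29, Per1 by 1.94 ± 0.24 and Tat by 1.21 ± 0.18. Of 21 genes of gluconeogenesis and amino acid breakdown 7 rose, or 8 adjusted over the list alone (median 0.24, adjusted p = 7.83e-05), with G6pc at 626 ± 148 against 191 ± 75.9 CPM (1.72 ± 0.30). Ppp1r3g, a glycogen-targeting phosphatase subunit, rose by 4.50 ± 0.57. Of 16 heat shock chaperones 5 fell, or 7 adjusted over the list alone (median -0.58, adjusted p = 2.44e-07, and adjusted p = 0.0596 with an estimated correlation), such as Hspa1b, which has a near-identical paralog (-2.82 ± 0.41), and Dnajb1 (-1.56 ± 0.22). Of 28 genes of fatty acid oxidation and PPARA targets 4 fell, or 5 adjusted over the list alone (median -0.34, adjusted p = 5.69e-05, and adjusted p = 0.282 with an estimated correlation). One of them, Acot1, fell by 1.68 ± 0.46 (adjusted p = 0.0155), a call lost without Alb CT4 21% B (adjusted p = 0.207, -1.09) or Alb CT4 6% C (adjusted p = 0.0742). Among the large falls were Phlda1, a regulator of cell death (-4.30 ± 0.71, 413 ± 241 to 20.3 ± 6.38 CPM), Cish, an inhibitor of STAT5 signalling (-3.63 ± 0.80), Foxa1, a liver transcription factor (-3.57 ± 0.46), and Gbp11, a GTPase (-3.16 ± 0.53). The Kupffer cell median of 1.13 and the endothelial median of 0.55 belong to the same libraries. In all 869 genes differed, 501 higher and 368 lower at 6% oxygen. The count was 497 without Alb CT4 21% B and 458 in a fit on the compared groups only.

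**Figure D3:**
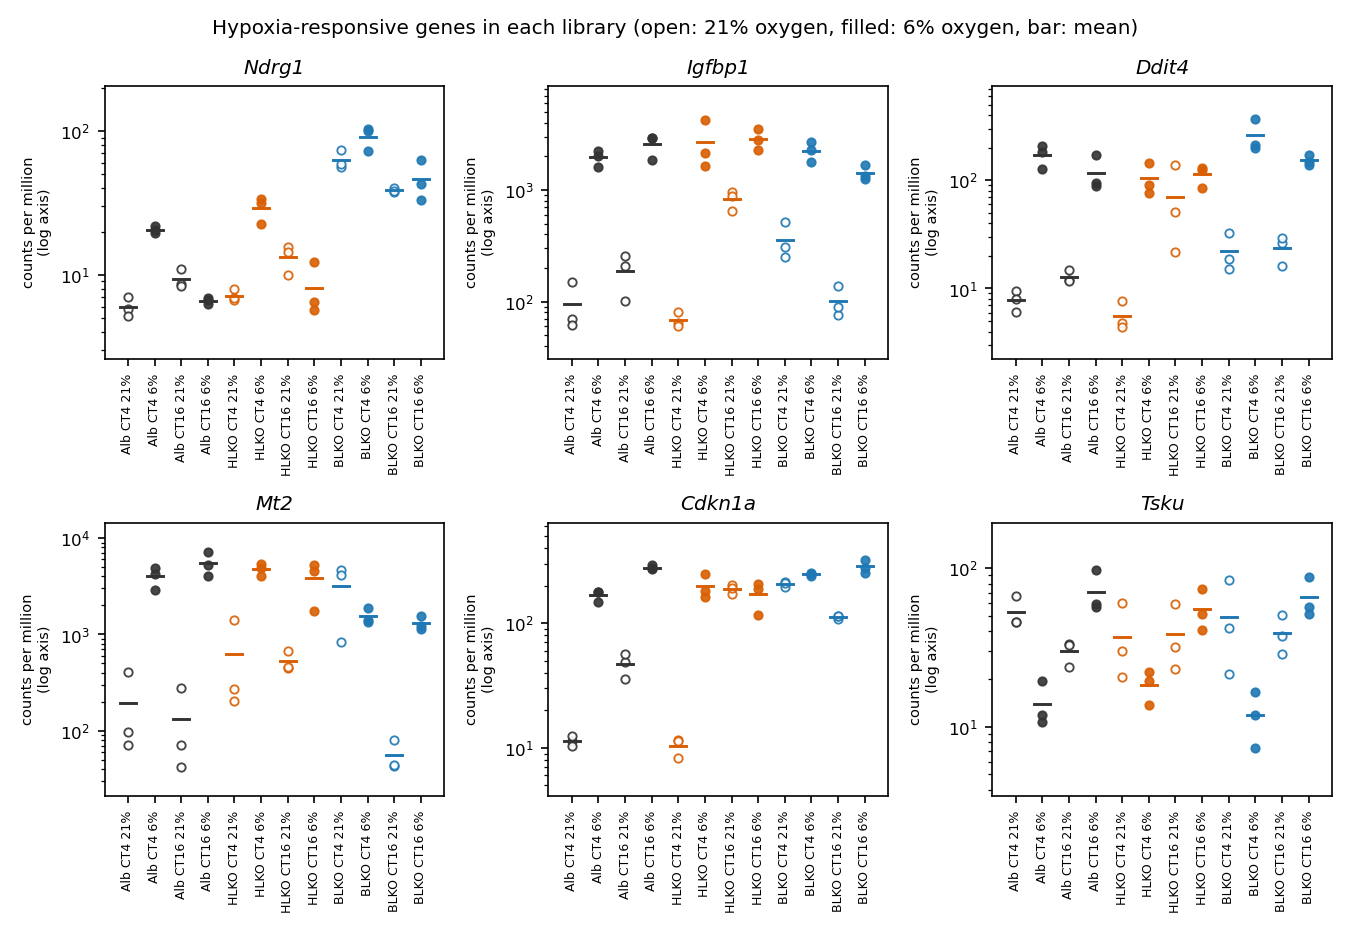
CPM of 6 genes in each of the 36 libraries (log axes), open points at 21% oxygen, filled points at 6% oxygen, bars at group means. Cdkn1a stands at 11.4 CPM in Alb CT4 21% and 10.4 CPM in HLKO CT4 21%, against 187 CPM in HLKO CT16 21% and 206 CPM in BLKO CT4 21%.

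At CT16, 6% oxygen raised some hypoxia-inducible, immediate early and lipid synthesis genes in Alb livers. Mt2 rose by 5.40 ± 0.75, Mt1 by 4.54 ± 0.63, Hilpda by 4.30 ± 0.56 and Igfbp1 by 3.77 ± 0.37. Of 29 HIF targets outside glycolysis 13 rose, with 16 higher and 1 lower adjusted over the list alone (median 0.60, adjusted p = 1.88e-08). Of 18 genes of glycolysis and glucose uptake 8 rose, with 9 higher and 1 lower adjusted over the list alone (median 0.50, adjusted p = 4.87e-05), such as Slc2a1 (1.69 ± 0.21) and Pkm (1.18 ± 0.22). Of 18 immediate early genes 11 rose, also adjusted over the list alone (median 1.76, adjusted p = 2.62e-10), with Btg2 at 3.85 ± 0.44, Ier3 at 3.76 ± 0.80 and Atf3 at 3.58 ± 0.72, and Gadd45b, a stress-induced gene, rose by 4.71 ± 0.43. Of 13 glucocorticoid targets 6 rose and 1 fell, also adjusted over the list alone (median 0.60, adjusted p = 1.88e-08), with Cdkn1a at 2.57 ± 0.17, Sgk1 at 1.98 ± 0.27, Tat at 1.78 ± 0.19 and Per1 at 1.39 ± 0.24. Of 21 genes of gluconeogenesis and amino acid breakdown 8 rose, also adjusted over the list alone (median 0.18, adjusted p = 6.28e-05), such as Sds, which breaks down serine (2.15 ± 0.22). Kupffer cell and macrophage markers had a median of 0.52, with 1 of 13 higher, or 0 adjusted over the list alone (adjusted p = 0.0278, and adjusted p = 0.63 with an estimated correlation).

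Some lipid genes rose in the Alb CT16 comparison. Srebf1, the transcriptional driver of lipid synthesis, went from 70.2 ± 20.9 to 563 ± 114 CPM (3.01 ± 0.24, adjusted p = 1.09e-10), Thrsp rose by 1.5 ± 0.23 and Fasn, fatty acid synthase, by 1.20 ± 0.28. Of 16 genes of fatty acid synthesis 5 rose, or 7 adjusted over the list alone (median 0.47, adjusted p = 6.52e-05, and 0.234 with an estimated correlation). Of 24 cholesterol synthesis genes 8 rose, or 12 adjusted over the list alone (median 0.54, adjusted p = 1.1e-06, and 0.103 with an estimated correlation). Of 12 clock genes driven by BMAL1, 4 rose, also adjusted over the list alone (median 0.61, adjusted p = 0.00217, and adjusted p = 0.0981 with an estimated correlation), with Ciart at 4.52 ± 0.50. Dbp rose by 1.4 ± 0.42 (adjusted p = 0.0239), a call lost without Alb CT16 21% A (adjusted p = 0.103) or C (0.0608) or without Alb CT16 6% C (0.103). Epas1 rose by 0.59 ± 0.13 (adjusted p = 0.00158). Vegfa was at 155 ± 69.0 against 103 ± 11.2 CPM (0.60 ± 0.21, adjusted p = 0.0535), and passed the threshold without Alb CT16 6% B (adjusted p = 0.0104) or C (0.0438). In the 6% group it was at 234 CPM in A, the replicate that stood apart, and at 103 and 130 CPM in B and C. Of 16 heat shock chaperones 5 fell, or 8 adjusted over the list alone (median -0.59, adjusted p = 3.54e-05, and 0.103 with an estimated correlation), such as Hspa1b (-2.73 ± 0.44). Among the large falls were Foxq1, a transcription factor (-4.29 ± 0.89), Cish (-3.61 ± 0.80), Phlda1 (-3.53 ± 0.69), Rgs3, a G protein regulator (-3.10 ± 0.45), and Foxa2, a liver transcription factor (-2.92 ± 0.32). In all 1278 genes differed, 637 higher and 641 lower at 6% oxygen.

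Whether the Alb response depends on time was asked by overlap and by an interaction test. The calls at the 2 times shared 248 genes higher and 211 genes lower in both, with 1 in opposite directions, where 33.7 and 24.9 would be shared by independent lists. The 501 genes higher at CT4 had a median of 0.66 at CT16, where 92.0% had the same sign. The interaction called 22 genes, 5 with a higher and 17 with a lower change at CT16. Tsku, a secreted regulator of lipid metabolism, was at 52.7 ± 12.2 CPM at 21% and 13.9 ± 4.70 CPM at 6% oxygen at CT4, and at 29.8 ± 5.11 and 71.2 ± 22.5 CPM at CT16 (difference 3.22 ± 0.57, adjusted p = 0.00907). Ndrg1 (chromosome 15, 66929318 to 66969640), a HIF target, was at 6.01 ± 0.96 and 20.5 ± 1.15 CPM at CT4 and at 9.35 ± 1.43 and 6.61 ± 0.34 CPM at CT16 (-2.26 ± 0.38, adjusted p = 0.00537). Por, the electron donor of cytochromes P450, differed by 1.27 ± 0.24 (adjusted p = 0.0219), a call lost without Alb CT16 21% C (adjusted p = 0.0654) or with the compared groups only (0.0592). For Per1 the difference was -0.54 ± 0.34 (adjusted p = 0.724). For Dbp it was 2.28 ± 0.55 (adjusted p = 0.0619), with an adjusted p of 0.014 without Alb CT4 6% B and 0.0338 by DESeq2. The 5 clock genes repressed by REV-ERB had a median difference of -1.03 (adjusted p = 2.43e-05). Over all genes edgeR called 0 of them, with 4 lower at an unadjusted p under 0.05 and 1 by DESeq2, and 4 were lower adjusted over the list alone. Among 16 genes of fatty acid synthesis 1 had a larger change at CT16, or 3 adjusted over the list alone (median 0.43, adjusted p = 9.52e-05, and adjusted p = 0.527 with an estimated correlation). The list of glycolysis and glucose uptake had a median of 0.24 and a mean of -0.01, opposite in sign, and its test pointed up (adjusted p = 0.0397, and adjusted p = 0.192 with an estimated correlation). Kupffer cell markers, of which 9 of 13 were higher at 6% oxygen in Alb CT4 (adjusted p = 0.124 for the list with an estimated correlation), had a median difference of -0.59 (adjusted p = 0.00642, and adjusted p = 0.799 with an estimated correlation). Liver endothelial markers had -0.39 (adjusted p = 0.00456, and 0.669 with an estimated correlation). The count of 22 was 8, 7 and 12 without Alb CT4 21% A, B and C, 14 without Alb CT4 6% B, 8, 9 and 6 without Alb CT16 21% A, B and C, and 11 without Alb CT16 6% B. It was 44 by DESeq2 and 2 in a fit on the compared groups only.

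**Figure D4:**
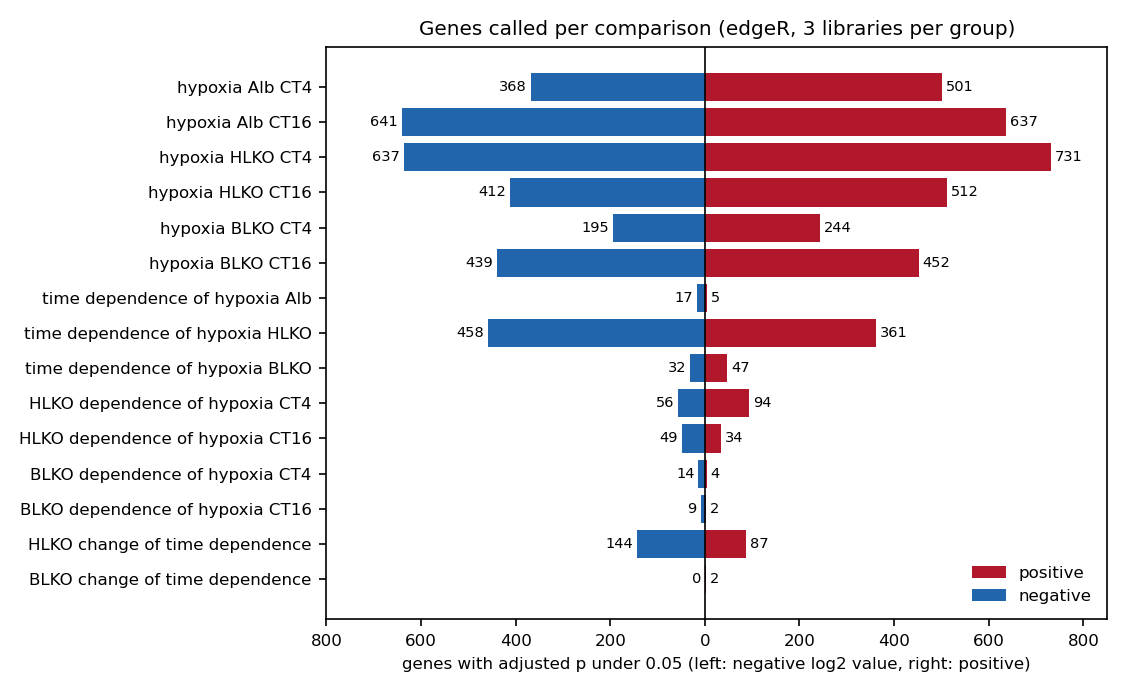
Number of called genes, higher and lower, for the comparisons drawn, at an adjusted p under 0.05. The 6 hypoxia comparisons call 439 to 1368 genes, and the time dependence of the hypoxia response calls 22 in Alb, 819 in HLKO and 79 in BLKO.

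The response to 6% oxygen without hepatocyte Hif1a was measured in HLKO mice. At CT4 Ppp1r3g rose by 5.60 ± 0.61, Igfbp1 by 5.31 ± 0.40 and Hilpda by 4.22 ± 0.59. Of 29 HIF targets outside glycolysis 15 rose, or 19 adjusted over the list alone (median 0.79, adjusted p = 1.35e-12). Vegfa was at 197 ± 55.8 against 134 ± 8.42 CPM (0.54 ± 0.21, adjusted p = 0.0737, and 0.0345 without HLKO CT4 6% A). Among 18 immediate early genes 12 rose, or 13 adjusted over the list alone (median 1.81, adjusted p = 1.74e-10), with Atf3 at 3.81 ± 0.72 and Nr4a1 at 3.39 ± 0.40. Of 13 glucocorticoid targets 9 rose, or 10 adjusted over the list alone (median 0.85, adjusted p = 2.97e-16): Pdk4 by 4.32 ± 0.64, Cdkn1a by 4.25 ± 0.20 (10.4 ± 1.85 to 197 ± 45.6 CPM), Sgk1 by 3.13 ± 0.31, Tat by 2.26 ± 0.19 and Per1 by 1.86 ± 0.24. Among 21 genes of gluconeogenesis and amino acid breakdown 9 rose, or 12 adjusted over the list alone (median 0.41, adjusted p = 4.11e-08), such as G6pc (2.42 ± 0.31). Among 28 genes of fatty acid oxidation and PPARA targets 7 rose, with 13 higher and 1 lower adjusted over the list alone (median 0.44, adjusted p = 0.00132, and adjusted p = 0.491 with an estimated correlation). Of 16 heat shock chaperones 7 fell, or 12 adjusted over the list alone (median -0.81, adjusted p = 5.32e-07, and adjusted p = 0.0572 with an estimated correlation), with Hspa1b at -2.78 ± 0.37 and Hsph1 at -2.0 ± 0.38. Among clock genes Arntl rose by 2.26 ± 0.43 (adjusted p = 0.000375) and Dbp fell by 2.27 ± 0.35 (291 ± 40.9 to 59.1 ± 32.4 CPM, adjusted p = 2.28e-05). Of 5 clock genes repressed by REV-ERB 2 rose, or 3 adjusted over the list alone (median 2.14, adjusted p = 0.00132). Gadd45b (5.17 ± 0.43) and the stress hormone Gdf15 (4.79 ± 0.37) rose. Camk2b (-4.71 ± 0.82), Cish (-4.07 ± 0.76), Phlda1 (-3.87 ± 0.69) and Cyp21a1, a steroid hydroxylase (-3.68 ± 0.64), fell. In all 1368 genes differed, 731 higher and 637 lower, and 903 without HLKO CT4 6% A.

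At CT16 immediate early genes and some lipid synthesis genes rose in HLKO at 6% oxygen, and some PPARA and glucocorticoid targets fell. Of 18 immediate early genes 15 rose and 1 fell, also adjusted over the list alone (median 2.20, adjusted p = 2.45e-22), with Atf3 at 5.62 ± 0.66, Btg2 at 3.98 ± 0.45 and Fos at 3.88 ± 0.58. Gdf15 rose by 4.70 ± 0.35 (36.5 ± 12.5 to 961 ± 155 CPM), Gadd45a, a stress sensor, by 4.54 ± 0.45, and Srebf1 by 3.15 ± 0.24. Among 16 genes of fatty acid synthesis 6 rose, or 7 adjusted over the list alone (median 0.29, adjusted p = 4.59e-06, and adjusted p = 0.23 with an estimated correlation), with Thrsp at 1.86 ± 0.23. Among 24 cholesterol synthesis genes 6 rose, or 7 adjusted over the list alone (median 0.30, adjusted p = 5.56e-06, and adjusted p = 0.23 with an estimated correlation), with Mvd, a mevalonate enzyme, at 2.41 ± 0.38. Of 28 genes of fatty acid oxidation and PPARA targets 11 fell, or 15 adjusted over the list alone (median -0.41, adjusted p = 1.32e-08, and adjusted p = 0.23 with an estimated correlation), such as Cyp4a14 (-5.65 ± 1.21, 536 ± 314 to 9.86 ± 5.96 CPM) and Cyp4a10 (-3.82 ± 0.84). Of 13 glucocorticoid targets 4 fell and 2 rose, with 5 and 2 adjusted over the list alone (median -0.45, adjusted p = 0.0389, and adjusted p = 0.23 with an estimated correlation), among the falls Fkbp5 (-1.45 ± 0.22) and Angptl4, a lipase inhibitor (-1.05 ± 0.25). Cdkn1a was at 170 ± 47.1 against 187 ± 16.5 CPM (-0.14 ± 0.16, adjusted p = 0.655) and Per1 at 60.5 ± 17.9 against 49.6 ± 7.31 CPM (0.26 ± 0.23, adjusted p = 0.519). Among 29 HIF targets outside glycolysis, 6 rose and 2 fell, with 8 and 3 adjusted over the list alone, and the list did not pass its test (median 0.01, adjusted p = 0.179, and adjusted p = 0.503 with an estimated correlation). Igfbp1 rose by 1.78 ± 0.34 (832 ± 169 to 2864 ± 603 CPM), Hilpda by 2.89 ± 0.58, and P4ha1, a collagen hydroxylase, fell by 1.90 ± 0.43. Vegfa was at 143 ± 36.7 against 98.3 ± 7.51 CPM (0.54 ± 0.21, adjusted p = 0.103). In all 924 genes differed, 512 higher and 412 lower. The count was 565 and 502 without HLKO CT16 21% A and B, 556 without HLKO CT16 6% A, and 421 in a fit on the compared groups only. Replicate C of the 6% group stood apart for genes chosen after their values were seen: Cish was at 75.8 CPM there and at 7.56 and 2.73 CPM in A and B, and Phlda1 at 286 CPM against 22.1 and 29.0 CPM.

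The HLKO response differed between the times in 819 genes by the interaction test, 361 with a higher and 458 with a lower change at CT16. Cdkn1a (-4.39 ± 0.26, adjusted p = 1.34e-13), Igfbp1 (-3.52 ± 0.48), Ddit4 (-3.48 ± 0.63), Ndrg1 (-2.70 ± 0.37), Tat (-2.35 ± 0.26) and Per1 (-1.60 ± 0.33, adjusted p = 0.00183) changed less, or the other way, at CT16. Of 13 glucocorticoid targets 11 had a lower change at CT16, or 12 adjusted over the list alone (median -1.57, adjusted p = 7.64e-21). So did 7 of 29 HIF targets outside glycolysis, or 8 adjusted over the list alone (median -0.57, adjusted p = 4.14e-06), and 6 of 21 genes of gluconeogenesis and amino acid breakdown, also adjusted over the list alone (median -0.40, adjusted p = 1.13e-05). Of 28 genes of fatty acid oxidation and PPARA targets 14 had a lower change, with 21 lower and 1 higher adjusted over the list alone (median -0.89, adjusted p = 3.53e-13, and adjusted p = 0.0714 with an estimated correlation), such as Cyp4a14 (-9.36 ± 1.90) and Cyp4a10 (-6.20 ± 1.23). Of 5 clock genes repressed by REV-ERB 4 had a lower change, also adjusted over the list alone (median -1.58, adjusted p = 0.000349), with Arntl at -2.66 ± 0.51, while Dbp differed by 3.61 ± 0.58. Large positive differences included those of Nrep, a neuronal protein (4.57 ± 0.48), Pttg1 (4.41 ± 0.56) and Angptl8, a lipase regulator (4.41 ± 0.70), and Mug2 had a negative one (-4.84 ± 0.71). Pttg1 was at 37.7 ± 0.29, 9.0 ± 1.39, 7.0 ± 1.15 and 37.2 ± 31.2 CPM in HLKO CT4 21%, CT4 6%, CT16 21% and CT16 6%, and Mug2 at 17.3 ± 4.44, 207 ± 30.2, 201.1 ± 178 and 82.4 ± 86.8 CPM. Among the 819 genes, 423 also differed between the times at 21% oxygen in the direction the difference needs, and 301 did so at 6% oxygen. The count was 492 without HLKO CT4 6% A, 463 without HLKO CT16 21% B, and 490 and 540 without HLKO CT16 6% A and C. Of the HLKO calls at the 2 times, 146 were higher in both and 99 lower in both, and 59 went in opposite directions, where independent lists would share 39.5 and 27.7.

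Whether Hif1a loss changes the response was tested as the difference between the HLKO and Alb responses. At CT4 it called 150 genes, 94 with a higher and 56 with a lower change in HLKO. Some PPARA targets had the larger change in HLKO: 6 of 28 did, or 19 adjusted over the list alone (median 0.69, adjusted p = 9.96e-13, and 0.18 with an estimated correlation), such as Acot1 (3.02 ± 0.63, adjusted p = 0.0139, lost without Alb CT4 21% B at 0.0887). Igsf11, a cell adhesion gene, differed by 3.35 ± 0.47 (adjusted p = 0.000462), while Camk2b (-5.16 ± 0.997), the amino acid transporter Slc43a1 (-2.38 ± 0.48, and adjusted p = 0.0574 without Alb CT4 21% B) and C4a, a complement gene with a close paralog (-2.18 ± 0.40), had a lower change. Camk2b was at 11.9 ± 3.18, 0.47 ± 0.42, 0.57 ± 0.30 and 7.28 ± 11.2 CPM in HLKO CT4 21%, CT4 6%, CT16 21% and CT16 6%. Of 13 Kupffer cell and macrophage markers 1 had a lower change, or 8 adjusted over the list alone (median -1.05, adjusted p = 4.68e-06, and 0.432 with an estimated correlation). In Alb CT4, 9 were higher at 6% oxygen (list adjusted p = 0.124 with an estimated correlation). Liver endothelial markers had a median difference of -0.44 (adjusted p = 0.0282, and adjusted p = 0.715 with an estimated correlation). At CT4 the count was 17 without Alb CT4 21% B, 61 without Alb CT4 6% B, 64, 99 and 73 without HLKO CT4 21% A, B and C, 59 and 82 without HLKO CT4 6% A and B, 234 by DESeq2 and 81 in a fit on the compared groups only.

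At CT16 the HLKO and Alb responses differed in 83 genes, 34 with a higher and 49 with a lower change in HLKO. Glucocorticoid targets had the lower change in HLKO, 3 of 13, or 10 adjusted over the list alone (median -1.05, adjusted p = 1.99e-23): Cdkn1a by -2.70 ± 0.23 (adjusted p = 5.06e-09), Fkbp5 by -1.92 ± 0.31 and Tat by -1.86 ± 0.26. The same list stood higher in HLKO than in Alb at CT16 21% (median 1.09). A lower change was found in 2 of 29 HIF targets outside glycolysis, or 3 adjusted over the list alone (median -0.64, adjusted p = 6.75e-06), and in 1 of 18 genes of glycolysis and glucose uptake, with 3 lower and 1 higher adjusted over the list alone (median -0.42, adjusted p = 0.000738). A lower change was also seen in 3 of 21 genes of gluconeogenesis and amino acid breakdown, with 6 lower and 1 higher adjusted over the list alone (median -0.32, adjusted p = 1.88e-05). Plin4, a lipid droplet protein (-3.27 ± 0.64, adjusted p = 0.00744, and 0.0607 with the compared groups only), and Lipg, a lipase (-2.59 ± 0.45), had a lower change, and Gbp11 a higher one (3.41 ± 0.64). Angptl8 differed by 3.72 ± 0.71 (adjusted p = 0.00602), but by 2.25 without HLKO CT16 6% C (adjusted p = 0.0828) and with an adjusted p of 0.0922 with the compared groups only. At CT16 the count was 31 and 36 without Alb CT16 21% A and C, 47 and 38 without Alb CT16 6% B and C, 37 and 42 without HLKO CT16 21% B and C, 159 and 21 without HLKO CT16 6% B and C, and 28 in a fit on the compared groups only.

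The 3-way test asked whether the time dependence itself differed between HLKO and Alb. It called 231 genes, 87 higher and 144 lower. Among 13 glucocorticoid targets 6 were lower, or 11 adjusted over the list alone (median -1.58, adjusted p = 5.45e-15). Among 29 HIF targets outside glycolysis 1 was lower, or 6 adjusted over the list alone (median -1.05, adjusted p = 1.56e-05), and 5 of 21 genes of gluconeogenesis and amino acid breakdown were, with 7 lower and 1 higher adjusted over the list alone (median -0.48, adjusted p = 0.000115). Among 28 genes of fatty acid oxidation and PPARA targets 7 were lower, or 20 adjusted over the list alone (median -1.06, adjusted p = 2e-12, and adjusted p = 0.107 with an estimated correlation). Plin4 differed by -5.22 ± 1.08, Acot1 by -4.73 ± 0.85, Angptl8 by 4.95 ± 0.98 and Pttg1 by 4.36 ± 0.71 (adjusted p = 0.000825). Kupffer cell markers had a median of 0.99 (adjusted p = 0.0255, and 0.656 with an estimated correlation). The count was 125 without Alb CT4 21% B, 141 without Alb CT16 21% A, 135 without Alb CT16 6% A, 141 without HLKO CT4 6% A, 147 without HLKO CT16 21% B, 521 without HLKO CT16 6% B and 133 without C, and 151 in a fit on the compared groups only.

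The response to 6% oxygen without hepatocyte Bmal1 was measured in BLKO mice. At CT4 Ppp1r3g rose by 3.80 ± 0.59, Ankrd37 by 3.75 ± 0.65, Ddit4 by 3.57 ± 0.42, Gdf15 by 3.28 ± 0.37 and Igfbp1 by 2.65 ± 0.35 (360 ± 141 to 2253 ± 471 CPM). Of 29 HIF targets outside glycolysis 7 rose, with 12 higher and 1 lower adjusted over the list alone (median 0.51, adjusted p = 4.76e-08). Vegfa was at 130 ± 28.0 against 80.4 ± 4.57 CPM (0.69 ± 0.21, adjusted p = 0.0602), and passed with DESeq2 (adjusted p = 0.0469), with the compared groups only (0.0217) and without BLKO CT4 6% C (0.039). Among 18 immediate early genes 5 rose and 1 fell, with 10 and 1 adjusted over the list alone (median 1.16, adjusted p = 2.8e-08, and adjusted p = 0.0738 with an estimated correlation), such as Klf4 (3.13 ± 0.56) and Nr4a1 (2.55 ± 0.39). Gadd45b rose by 3.34 ± 0.50. Of 25 acute phase proteins 6 fell, or 13 adjusted over the list alone (median -0.89, adjusted p = 1.47e-12, and adjusted p = 0.193 with an estimated correlation). Among 16 heat shock chaperones 3 fell, or 7 adjusted over the list alone (median -0.35, adjusted p = 3.59e-05, and adjusted p = 0.18 with an estimated correlation). Scara5, a ferritin receptor (-3.33 ± 0.51), and Inhbe, a liver activin subunit (-3.05 ± 0.42), fell. Phlda1 fell by 3.01 ± 0.67 (adjusted p = 0.00554), a call lost without BLKO CT4 21% A (adjusted p = 0.0598). Per1 rose by 0.99 ± 0.25 (adjusted p = 0.0139), lost without BLKO CT4 21% A (0.061) or C (0.0518) or BLKO CT4 6% A (0.103) or B (0.0523). In all 439 genes differed, 244 higher and 195 lower. The count was 270 and 260 without BLKO CT4 21% A and B, and 282 and 284 without BLKO CT4 6% A and C.

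At CT16 in BLKO, Mt2 rose by 4.56 ± 0.72 (55.7 ± 20.9 to 1313 ± 228 CPM), Mt1 by 4.30 ± 0.63, Ppp1r3g by 4.23 ± 0.67, Igfbp1 by 3.80 ± 0.37, Gdf15 by 3.39 ± 0.35, Cyp26b1, which clears retinoic acid, by 3.25 ± 0.53, and Ddit4 by 2.70 ± 0.40. Slc2a1 rose by 1.254 ± 0.21. Of 29 HIF targets outside glycolysis 5 rose and 1 fell, with 6 and 1 adjusted over the list alone (median 0.26, adjusted p = 0.00457, and adjusted p = 0.126 with an estimated correlation). Among 18 immediate early genes 9 rose and 1 fell, with 11 and 1 adjusted over the list alone (median 1.47, adjusted p = 4.82e-08, and adjusted p = 0.111 with an estimated correlation). Among 19 genes of the integrated stress and unfolded protein response 7 rose, with 8 higher and 1 lower adjusted over the list alone (median 0.53, adjusted p = 5.45e-05, and adjusted p = 0.111 with an estimated correlation), with the stress kinase homolog Trib3 at 2.05 ± 0.50. Of 16 heat shock chaperones 7 fell, or 9 adjusted over the list alone (median -0.33, adjusted p = 2.98e-06, and adjusted p = 0.111 with an estimated correlation), with Hspa1b at -1.68 ± 0.34 and Dnajb1 at -1.34 ± 0.20. Vegfa was at 101.2 ± 3.29 against 89.0 ± 10.8 CPM (0.18 ± 0.21, adjusted p = 0.677) and Per1 at 31.6 ± 8.13 against 26.9 ± 7.10 CPM (0.24 ± 0.23, adjusted p = 0.615). The transcription factors Sox18 (-3.13 ± 0.58) and Hhex (-2.75 ± 0.43) and the Wnt regulator Rnf43 (-2.67 ± 0.45) fell. Cish fell by 4.33 ± 1.03 (adjusted p = 0.00561), and was at -2.99 without BLKO CT16 21% A (adjusted p = 0.134). In all 891 genes differed, 452 higher and 439 lower. The count was 585 without BLKO CT16 21% A, and 577 and 567 without BLKO CT16 6% A and B.

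**Figure D5:**
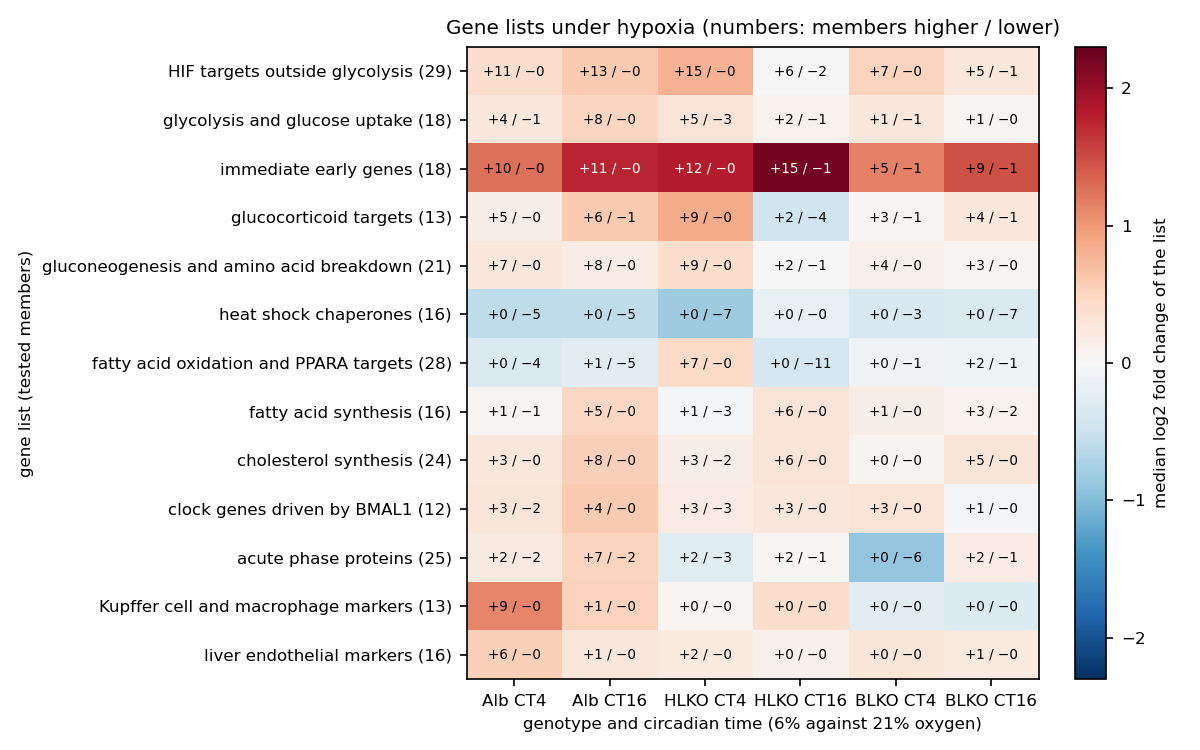
Median log2 fold change at 6% against 21% oxygen of 13 gene lists (lines) in the 6 hypoxia comparisons (columns), with the number of called members higher and lower printed in each cell. Immediate early genes have medians of 1.27 and 1.76 in Alb, 1.81 and 2.20 in HLKO, and 1.16 and 1.47 in BLKO at CT4 and CT16.

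The BLKO response differed between the times in 79 genes, 47 with a higher and 32 with a lower change at CT16. Mt2 (5.62 ± 0.94), Mt1 (5.03 ± 0.82) and Tacc2 (3.01 ± 0.53, adjusted p = 0.00611) had the higher change. Mt2 was at 3205 ± 2070 CPM in BLKO CT4 21%, 1538 ± 283 in CT4 6%, 55.7 ± 20.9 in CT16 21% and 1313 ± 228 in CT16 6%. Among 25 acute phase proteins, a list that holds Mt1 and Mt2, 4 had a higher change, or 9 adjusted over the list alone (median 0.92, adjusted p = 1.53e-14, and adjusted p = 0.37 with an estimated correlation). Gas1, a growth arrest gene, differed by -2.70 ± 0.56 (adjusted p = 0.0169, and 0.0663 without BLKO CT4 6% C). The count was 27 and 38 without BLKO CT4 21% A and B, 50, 42 and 5 without BLKO CT4 6% A, B and C, 46 and 48 without BLKO CT16 21% A and B, and 34 and 41 without BLKO CT16 6% B and C.

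Whether Bmal1 loss changes the response was tested as the difference between the BLKO and Alb responses. At CT4 it called 18 genes, 4 with a higher and 14 with a lower change in BLKO. Cdkn1a differed by -3.62 ± 0.25 (adjusted p = 1.57e-11), Mt2 by -5.44 ± 0.93 and Fam222a, a little-studied gene, by -2.98 ± 0.47, and all of them stood higher in BLKO CT4 21% (206 ± 11.0, 3205 ± 2070 and 35.0 ± 10 CPM) than in Alb CT4 21% (11.4 ± 1.07, 192 ± 188 and 5.15 ± 1.43 CPM). Among 13 glucocorticoid targets 2 had a lower change, or 5 adjusted over the list alone (median -0.60, adjusted p = 1.89e-10). Among 25 acute phase proteins 3 did, or 13 adjusted over the list alone (median -0.94, adjusted p = 1.89e-17, and adjusted p = 0.14 with an estimated correlation). Kupffer cell and macrophage markers had a median difference of -1.49, with 0 of 13 called by edgeR, 9 lower at an unadjusted p under 0.05, 1 by DESeq2 and 9 adjusted over the list alone (adjusted p = 4.69e-11, and adjusted p = 0.14 with an estimated correlation). Liver endothelial markers had a median difference of -0.35 (adjusted p = 0.016, and 0.593 with an estimated correlation). In Alb CT4 itself, 9 of 13 Kupffer cell markers and 6 of 16 endothelial markers were higher at 6% oxygen, and both lists lost their call with an estimated correlation (adjusted p = 0.124 and adjusted p = 0.117). The CT4 count was 67, 5 and 4 without Alb CT4 21% A, B and C, 7 without Alb CT4 6% A, 5 and 11 without BLKO CT4 21% A and B, 9 and 5 without BLKO CT4 6% A and C, 50 by DESeq2 and 5 in a fit on the compared groups only.

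At CT16 the BLKO and Alb responses differed in 11 genes, 2 with a higher and 9 with a lower change in BLKO. Sgk1 (-2.40 ± 0.36, adjusted p = 0.00184) was at 76.0 ± 18.2 CPM at 21% and 56.5 ± 9.44 CPM at 6% oxygen in BLKO, and at 14.5 ± 4.38 and 58.1 ± 19.0 CPM in Alb. Noct, a circadian phosphatase, differed by -2.45 ± 0.43 (adjusted p = 0.0121, and 0.0517 without Alb CT16 21% A). Cdkn1a differed by -1.22 ± 0.23 (adjusted p = 0.0183), lost without Alb CT16 21% A (adjusted p = 0.103) or BLKO CT16 6% B (0.0566) or C (0.0675). Several lists had a lower change in BLKO also with an estimated correlation. They were glucocorticoid targets (3 of 13, 4 adjusted over the list alone, median -0.46, adjusted p = 1.1e-05), cell cycle genes (1 of 11, 3 adjusted over the list alone, median -0.86, adjusted p = 2e-07) and genes of gluconeogenesis and amino acid breakdown (1 of 21, 4 adjusted over the list alone, median -0.26, adjusted p = 1.1e-05). The called cell cycle gene was Cdkn1a, a cell cycle inhibitor that is also counted among the glucocorticoid targets. In 4 further lists that passed with an estimated correlation edgeR called 0 members. They were clock genes driven by BMAL1 (median -0.74, adjusted p = 3.64e-05, 4 lower at an unadjusted p under 0.05, 3 adjusted over the list alone, 0 by DESeq2) and glycolysis and glucose uptake (median -0.38, adjusted p = 0.000103, 5 lower unadjusted, 2 adjusted over the list alone, 0 by DESeq2). The others were HIF targets outside glycolysis (median -0.41, adjusted p = 0.000111, 6 lower and 2 higher unadjusted, 1 adjusted over the list alone, 1 by DESeq2) and nitric oxide and vascular tone (median -0.35, adjusted p = 0.00211, 5 lower unadjusted, 2 adjusted over the list alone, 0 by DESeq2). Kupffer cell markers had a median difference of -0.95 at CT16 (adjusted p = 2.62e-06, and 0.188 with an estimated correlation). The CT16 count was 1, 5 and 5 without Alb CT16 21% A, B and C, 5 and 7 without Alb CT16 6% A and C, 7 and 17 without BLKO CT16 21% A and B, 7, 2 and 3 without BLKO CT16 6% A, B and C, and 23 by DESeq2.

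The 3-way test for BLKO against Alb called 2 genes, Cdkn1a (2.39 ± 0.34, adjusted p = 0.000548) and Atg13, an autophagy initiator (1.33 ± 0.24, adjusted p = 0.0208). The call of Atg13 was lost without Alb CT4 21% B (adjusted p = 0.0502) or C (0.0501), Alb CT4 6% A (0.0604), Alb CT16 21% A (0.0745), Alb CT16 6% C (0.0505), BLKO CT4 21% A (0.0741), BLKO CT4 6% A (0.053) or C (0.0573), or BLKO CT16 21% A (0.0596) or C (0.0525), and without a low-count filter (0.0569). The count of 2 was 1 without Alb CT4 21% B, Alb CT4 6% A, Alb CT16 21% A, Alb CT16 6% C, BLKO CT4 21% A, BLKO CT4 6% C, BLKO CT16 21% A or BLKO CT16 21% C. It was 4 without Alb CT4 21% A or BLKO CT4 21% B, 8 and 12 without Alb CT4 6% B and C, and 7 without Alb CT16 21% C or BLKO CT4 21% C. It was 24 by DESeq2, 6 in a fit on the compared groups only and 1 without a low-count filter. Acute phase proteins had a median of 0.60, with 0 of 25 called by edgeR, 7 higher at an unadjusted p under 0.05, 0 by DESeq2 and 7 adjusted over the list alone (adjusted p = 2.37e-05, and adjusted p = 0.537 with an estimated correlation). Kupffer cell markers had a median of 0.34 (adjusted p = 0.172). Over the 6 hypoxia comparisons, 56 genes were called higher in all and 33 lower in all, with 0 of mixed direction among the genes called in every comparison.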

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

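The tests of genes near the floxed loci, the counts per chromosome, and the comparison of the times at 21% with the times at 6% oxygen were chosen only after the results were seen.

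Each value in this paragraph and the next was picked out because the response to 6% oxygen differed between times or genotypes by an interaction test. Groups hold 3 libraries, too few for an outlier test. By edgeR at an adjusted p under 0.05 the responses differed between the times in 22 genes in Alb (6 without Alb CT16 21% C, 23 without Alb CT4 6% A), 819 in HLKO (463 without HLKO CT16 21% B, 1221 without HLKO CT16 6% B) and 79 in BLKO (5 without BLKO CT4 6% C, 75 without BLKO CT4 21% C). HLKO differed from Alb in 150 genes at CT4 (17 without Alb CT4 21% B, 186 without C) and 83 at CT16 (21 without HLKO CT16 6% C, 159 without B). BLKO differed from Alb in 18 genes at CT4 (4 without Alb CT4 21% C, 67 without A) and 11 at CT16 (1 without Alb CT16 21% A, 17 without BLKO CT16 21% B). The change in time dependence covered 231 genes in HLKO (125 without Alb CT4 21% B, 521 without HLKO CT16 6% B) and 2 in BLKO (1 without Alb CT4 21% B, 12 without Alb CT4 6% C).

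As log2 differences of the responses, CT16 less CT4 was -2.26 for Ndrg1, 1.27 for Por and 3.22 for Tsku in Alb. In HLKO it was 4.41 for Angptl8, -2.66 for Arntl, -4.39 for Cdkn1a, -6.2 for Cyp4a10, -9.36 for Cyp4a14, 3.61 for Dbp, -3.48 for Ddit4, -3.52 for Igfbp1, -4.84 for Mug2, -2.7 for Ndrg1, 4.57 for Nrep, -1.6 for Per1, 4.41 for Pttg1 and -2.35 for Tat. In BLKO it was -2.7 for Gas1, 5.03 for Mt1, 5.62 for Mt2 and 3.01 for Tacc2. HLKO less Alb at CT4 was 3.02 for Acot1, -2.18 for C4a, -5.16 for Camk2b, 3.35 for Igsf11 and -2.38 for Slc43a1. At CT16 it was 3.72 for Angptl8, -2.7 for Cdkn1a, -1.92 for Fkbp5, 3.41 for Gbp11, -2.59 for Lipg, -3.27 for Plin4 and -1.86 for Tat. BLKO less Alb was -3.62 for Cdkn1a, -2.98 for Fam222a and -5.44 for Mt2 at CT4, and -1.22 for Cdkn1a, -2.45 for Noct and -2.4 for Sgk1 at CT16. The 3-way difference was -4.73 for Acot1, 4.95 for Angptl8, -5.22 for Plin4 and 4.36 for Pttg1 in HLKO, and 1.33 for Atg13 and 2.39 for Cdkn1a in BLKO. Lists past the test of camera also with an estimated correlation had these median differences. Between the times, clock genes repressed by REV-ERB had -1.03 in Alb and -1.58 in HLKO, where HIF targets outside glycolysis had -0.57, gluconeogenesis -0.4 and glucocorticoid targets -1.57. HLKO less Alb at CT16 had -0.42 for glycolysis, -0.64 for HIF targets, -0.32 for gluconeogenesis and -1.05 for glucocorticoid targets. BLKO less Alb had -0.6 for glucocorticoid targets at CT4. At CT16 it had -0.38 for glycolysis, -0.41 for HIF targets, -0.74 for clock genes driven by BMAL1, -0.26 for gluconeogenesis, -0.46 for glucocorticoid targets, -0.35 for nitric oxide and vascular tone and -0.86 for the cell cycle. The 3-way difference of HLKO had -1.05 for HIF targets, -0.48 for gluconeogenesis and -1.58 for glucocorticoid targets.

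The HLKO response differed between the times in many more genes than the Alb response. A single deviating library is argued against, since the count stayed at 463 or more with any HLKO library left out. Blocks of linked alleles that differ between the mice of the HLKO groups are argued against as the main source. Called genes lay within 1 Mb of each other 0.991 times as often as in random sets, against 1.22 and 1.2 for Alb hypoxia calls. The time calls of HLKO at 21% oxygen gave 1.14, and a smaller contribution of such blocks is not excluded. Shifts were seen both between the 21% groups of HLKO and between its 6% groups. Of the 819 genes, 423 differed between the times at 21% oxygen in the direction needed, and 301 did so at 6% oxygen. The ratio of 1.41 (0.467 in Alb, 0.8 in BLKO) fell short of the 2-fold excess set for a shift mainly at 21% oxygen. The ratio therefore does not decide which side weighs more. An effect of Hif1a loss, which the design names, and a difference in feeding or collection day, which no label gives, stay open and were not tested.

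Genes that differed between HLKO and Alb at both times at 21% oxygen were frequent on chromosome 12, with 16 of 93 (17.2%) against 3.54% of tested genes (one-sided Fisher p = 1.37e-07, adjusted p = 5.76e-06 over 42 tests, which treat neighbouring genes as independent). A segment carried with the floxed Hif1a allele could contribute. Within 25 Mb of Hif1a the share was 2.68 times that of tested genes (4 genes, Fisher's exact p = 0.0623), but around Arntl, which is not floxed in HLKO, it was 2.92 times (7 genes, exact p = 0.0101). Segment and Hif1a loss cannot be told apart, because line and genotype coincide and 4 genes are few.

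For BLKO against Alb the share within 25 Mb of Arntl was 1.23 times that of tested genes (7 of 220, Fisher's exact p = 0.34), and 0.849 times around Hif1a (exact p = 0.691), while chromosome 19 held 19 of 220 (adjusted p = 0.0158). A segment carried with the floxed Bmal1 allele and Bmal1 loss cannot be told apart for the 7 genes there, one of which is Trim12a. Trim12a was near 0 in both knockout lines, so an allele of the background that both share is a candidate explanation, which was not tested.

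Other splits of the same libraries were fitted on the compared groups only. For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. Called genes in the real split and in the highest other were 458 and 0 for hypoxia in Alb CT4, 913 and 1 in Alb CT16, 1350 and 0 in HLKO CT4, 421 and 1 in HLKO CT16, 401 and 1 in BLKO CT4, and 819 and 0 in BLKO CT16. At 21% oxygen they were 743 and 0 for HLKO against Alb at CT4, 483 and 0 at CT16, 522 and 0 for BLKO against Alb at CT4, 488 and 0 at CT16, 69 and 1 for time in Alb, 1159 and 1 in HLKO, and 196 and 0 in BLKO. With 100 splits the share as large was under 0.05 for the time dependence in HLKO (659 genes, highest other 447, 1 split as large, the real one) and BLKO (100, 40, 1), for HLKO against Alb at CT4 (81, 609, 3) and CT16 (28, 24, 1), for BLKO against Alb at CT16 (9, 287, 4) and for the change in time dependence of HLKO (151, 78, 1). Chance is not excluded for the time dependence in Alb (2, 372, 17), BLKO against Alb at CT4 (5, 935, 9) or the change in time dependence of BLKO (6, 506, 5). Some splits called several times the real count, here 372, 609, 935, 287 and 506. Labels of time or genotype were exchanged separately at each oxygen level, so some splits put time or genotype effects into the contrast. Why these splits called so many genes was not tested. Splits that mix the groups also put the effects of oxygen, time and genotype into the spread (the other splits had a median of 0 calls), and the 9 shares are unadjusted, so a share under 0.05 does not exclude chance here.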

How the results depend on the processing

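The alternatives were chosen before the data were examined, and the cause of a change was not tested except where a stricter threshold gives it. The 22 counts, the number of lists that passed and the overlap of the Alb calls had 323 values under these choices. Of these 193 stayed within 1.5 times the reported count, 114 were lower and 16 higher. With RLE normalization and with a replicate block every count stayed within 1.5 times. With RLE normalization the median change of all genes moved by at most 0.0247 and the share of higher genes by at most 4.1 percentage points. A fit on the compared groups only, with fewer libraries to estimate the spread, gave 458 instead of 869 genes for hypoxia in Alb CT4, 421 instead of 924 in HLKO CT16, 2 instead of 22 for the time dependence in Alb, 81 instead of 150 and 28 instead of 83 for HLKO against Alb at CT4 and CT16, 5 instead of 18 for BLKO against Alb at CT4, 151 instead of 231 and 6 instead of 2 for the change in time dependence of HLKO and BLKO, and 69 instead of 120 for time in Alb at 21%. DESeq2 gave fewer genes in all 6 hypoxia comparisons, within 1.5 times, and over 1.5 times as many in these: 44 for the time dependence in Alb, 234 for HLKO against Alb at CT4, 50 and 23 for BLKO against Alb at CT4 and CT16, and 24 for the change in BLKO. Without a low-count filter the last was 1. Leaving out 1 library, which leaves 2 in a group, gave 497 (without Alb CT4 21% B) to 777 genes for hypoxia in Alb CT4, 865 to 1228 in Alb CT16, 903 (HLKO CT4 6% A) to 1163 in HLKO CT4, 502 (HLKO CT16 21% B) to 1021 in HLKO CT16, 260 (BLKO CT4 21% B) to 357 in BLKO CT4 and 567 (BLKO CT16 6% B) to 668 in BLKO CT16. For the time dependence it gave 6 (Alb CT16 21% C) to 23 in Alb, 463 (HLKO CT16 21% B) to 1221 in HLKO and 5 (BLKO CT4 6% C) to 75 in BLKO. For HLKO against Alb it gave 17 (Alb CT4 21% B) to 186 at CT4 and 21 (HLKO CT16 6% C) to 159 at CT16, and for BLKO against Alb 4 (Alb CT4 21% C) to 67 and 1 (Alb CT16 21% A) to 17. The change in time dependence ran from 125 (Alb CT4 21% B) to 521 in HLKO and from 1 (8 different libraries) to 12 in BLKO. At 21% oxygen the range was 277 (Alb CT4 21% B) to 793 and 126 (Alb CT16 21% A) to 298 for HLKO against Alb, 423 (BLKO CT4 21% A) to 631 and 270 (BLKO CT16 21% B) to 438 for BLKO against Alb, at CT4 and CT16. For time it was 39 (Alb CT16 21% C) to 111 in Alb, 677 (HLKO CT16 21% B) to 981 in HLKO and 73 (BLKO CT4 21% A) to 145 in BLKO. Of 660 tests of lists 176 passed, and 50 with an estimated correlation. With a replicate block 180 passed, of which 175 were shared. The overlap of the Alb calls at the 2 times was 459 genes, and 225 at an adjusted p under 0.01, a threshold that admits fewer genes. For single genes, 252 results in the text had 3124 values under alternatives, of which 51 lost and 10 gained a call and 0 reversed. Among these, 226 results kept their side of the threshold throughout, and 15 of the other 26 changed only when 1 library was left out. Genes were named partly because their calls held when each library was left out, so these tallies do not measure stability. Depth limits what can be said of genes near the floor of 3 counts.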

Other observations

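A set of genes, chosen after their values were seen, responded to 6% oxygen in every genotype and at both times. Among the 56 genes called higher by edgeR in all 6 comparisons were Ppp1r3g (lowest and highest change 3.19 and 5.6), Gdf15 (3.13 and 4.79), the transcription factors Maff (2.52 and 3.78) and Klf4 (1.99 and 3.17), Gadd45b (2.14 and 5.17), the cold-inducible RNA-binding protein Cirbp (1.47 and 2.54), Txnip, an inhibitor of glucose uptake (1.33 and 2.44), and Bhlhe40, a clock repressor and HIF target (0.949 and 2.35). The 33 called lower in all included Foxa1 (falls of 1.61 and 3.57), Clec2d, a ligand of natural killer receptors (1.29 and 2.78), the interferon signal carrier Stat2 (0.798 and 1.87), Mcl1, which restrains cell death (0.556 and 1.35), and the splicing factor Rbm5 (0.831 and 1.23).

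The sign of the response was compared between groups, as shares of genes without a test. Of 731 genes higher in HLKO CT4, 59.6% had the same sign in HLKO CT16 (median 0.153), 76.6% in Alb CT4 (median 0.374) and 77.2% in Alb CT16 (median 0.437), and of 637 lower genes 65.5%, 77.7% and 76.3%. Of 512 genes higher in HLKO CT16, 68.2% had the same sign in HLKO CT4 (median 0.241), 90% in Alb CT16 (median 0.501) and 89.6% in Alb CT4 (median 0.472), and of 412 lower genes 60.9%, 91.3% and 88.3%.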
